A study of Mus musculus with 2 samples.

How the data were processed

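DNase-seq libraries from the urinary bladder of 2 female B6CASTF1/J mice aged 36 days were analysed, 1 library per animal. Per the labels, they are biological replicates 1 and 2 from separate biosamples of the same tissue, and each has a single technical replicate. They form 1 group without a control or a second condition, so no test between groups was possible, and the spread between the animals is the only replicate error. Because both libraries share a strain-level donor record in the labels, only the separate biosamples and animal numbers in the labels state that the animals are distinct.

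The authors deposited, for each animal, 2 lists of peaks, a list of footprints and a list of bases with their false discovery rate, all on mm10 per the labels. Peak height is a signal that the authors computed for each peak from that animal's alignments, and its scaling, the aligner, the peak caller and its threshold are not given in the sources used here. Every height in the deposited lists is a whole multiple of a step within 0.05 of a step (100% in both animals), with steps of 0.00789 and 0.00849. The lowest heights are 8 and 5 steps. If the unit is RPM, the steps correspond to 127 and 118 M reads. Other columns of the deposited peak lists hold a constant and were not used. The deposited p-value type columns are the false discovery rate of the local cut rate, up to 0.05, and a threshold of 0.01 that is the same for every footprint. Footprints could therefore not be ranked. Per the deposited description of each sample, peaks and footprints were called in each animal separately. The description itself holds no measurement and was not used otherwise.

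Before the data were examined, the groups, the tests, 19 gene lists with 245 genes (16 cell type and control lists and 3 Hox lists), 22 consensus motifs, the rule for naming genes and most alternatives were fixed. The larger peak list of each animal was taken as the main list after list sizes and footprint positions were looked at and before any result was computed. All of its peaks touch a region at a false discovery rate up to 0.05 (100% in both animals), while 64.8% and 62.7% touch a region at 0.001. The smaller lists, with 73247 and 61717 peaks, touch regions at 0.001 in 100% of cases and served as an alternative.

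Peaks were handled with bedtools 2.31.1, samtools 1.23.1 and pysam 0.24.0, and values with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes and sequence came from GRCm38 with the GENCODE annotation, whose chromosome names and lengths were checked against the peak coordinates. Chromosomes 1 to 19, X and Y were kept. Peaks overlapped when they shared at least 1 bp, and chance overlap was the mean of 100 random placements of each peak on its own chromosome. Heights were correlated over pairs of overlapping peaks. A promoter was 1 kb on either side of the most upstream annotated start of a gene, so a gene that mainly uses an inner start can appear closed. Promoter height was that of the highest peak touching this window, and that peak can lie away from the gene start. Distal density was the number of peaks per 10 kb in the gene body and 10 kb on either side, without the gene's own promoter. The difference between animals was the log2 ratio of summed heights over the same domain with a pseudocount of 1, relative to the median of all genes. Such sums move with the amount of sequence called as peaks, so covered length and mean height are given with them.

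A list stood apart when its value lay at or above percentile 99 or at or below percentile 1 of 10000 random lists of the same size in both animals. Random lists were matched on gene length, or on mean signal for the difference between animals, where a single percentile was computed. Percentiles describe these libraries and are not p-values. The 19 lists were each examined for 3 measures, apart from the Hox promoter shares, which form a family of their own. Footprint overlap was compared with 20 random placements of each footprint within its own peak. Motif matches on both strands were counted in footprints extended by 5 bp against the rest of the same peaks, and in 75 bp on either side of peak midpoints against flanks 1 kb away. Intervals at 95% came from 1000 bootstrap draws of 20 chromosomes. A motif was called when the interval lay on one side of 1 in both animals and, by a rule added after the data were seen, when at least 20 matches were counted. Copies of the highest peaks were sought with blastn 2.17.0 at 90% identity over 80% of the length.

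Named genes were a fixed set (Upk1a, Upk2, Upk3a, Krt5, Krt20, Trp63, Pparg, Foxa1, Gata3, Acta2, Myh11, Actg2, Col1a1, Pdgfra, Pecam1, Ptprc, Hoxa13, Hoxd13, Xist, Alb and Ins2, and a further gene that is not reported here). To these were added the 2 members of each list with the highest distal density and the 1 with the lowest, the genes nearest the 10 highest shared peaks, the 10 genes with the most shared distal peaks, and the genes nearest the 5 highest peaks private to each animal. Private peaks overlapped neither a peak nor a region at a false discovery rate up to 0.05 of the other animal. Genes outside the rule are said to be chosen after their values were seen.

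The programs were tested on simulated data with fixed seeds. For 117773 simulated peaks with a planted overlap of 60.5%, the overlap found was 61.0%. Among 200 random lists of unchanged density over 21728 genes, 3% were called in a single library. With 14 genes per list, planted increases in distal density of 1.5, 2 and 3 times were called in 40%, 77.5% and 97.5% of lists. Genes below the median density were first raised to the median, and calls were made in a single library. These shares may therefore be too high for the rule used here, which asks for both animals. The motif counter found 618 matches where 614 were planted in random sequence.

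Alternatives were the smaller peak list, the higher 50% of the peaks, stricter overlap, equal numbers of peaks, other promoter windows, gene starts and domains, lists matched on GC content, peaks found in both animals for distal density, peak counts, quantile scaling, another pseudocount, other footprint and motif windows, reversed motifs and each replicate left out. Added after the data were seen were overlap with regions at a false discovery rate up to 0.05, scaling by GC content and peaks shared by both animals for the difference between animals, random runs of neighbouring genes for the Hox lists, and the 3 gene lists of the closing section. Those lists were 30 further epithelial genes, 68 other developmental regulators and 6 genes that escape X inactivation. Reads were not used here, so cut bias, duplicate reads and the mapping of the CAST alleles to the reference could not be examined. Gene expression was not analysed here.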

Results

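DNase-seq was carried out on urinary bladder tissue of 2 female mice aged 36 days. In this assay nuclei are digested lightly with deoxyribonuclease I, and the cut ends are sequenced so that open, protein-accessible DNA stands out. The strain, B6CASTF1/J, is a first-generation hybrid between a common laboratory strain and the wild-derived CAST strain. The labels number the animals 5 and 6 and give each its own biosample, and they are called replicate 1 and replicate 2 here. Both belong to a single group with no treatment and no second tissue, so the data allow a description of the open sites of the bladder and a comparison of the animals with each other. With 1 library per animal no p-value was computed. Peak heights are the authors' own values. They moved in steps of 0.00789 in replicate 1 and 0.00849 in replicate 2, and 100% of the heights were whole multiples of the step within 0.05 of a step. If heights are RPM values, which the sources used here do not state, these steps correspond to about 127 and 118 M reads.

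The open sites of the bladder lay disproportionately at gene starts. Promoters, the 1 kb on either side of an annotated gene start, held 19.95% ± 1.03 of the peaks (SD, n = 2) against 1.68% for the same peaks placed at random on their own chromosomes. Exons outside promoters held 6.58% ± 0.20 against 3.53% by chance, introns 36.0% ± 0.92 against 37.0%, and intergenic DNA 37.4% ± 0.31 against 57.8%. Promoter peaks were also the highest, with a median height of 1.97 in replicate 1 and 1.78 in replicate 2, compared with 0.718 and 0.612 for intergenic peaks. Of the peaks in the highest decile of height, 67.2% and 72.8% lay at promoters. Replicate 1 had 117773 peaks and replicate 2 had 102671 (110222 ± 10679, SD, n = 2), with median widths of 182 and 200 bp. They covered 22.4 and 22.6 Mb, or 0.847% and 0.855% of the genome. Of 21728 protein-coding genes, 13601 (62.6%) had a promoter peak in both animals. The smaller of the authors' 2 peak lists and the higher 50% of the peaks had larger shares of promoter peaks, 27.3% and 30.03%.

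Most open regions of the bladder were found in both animals. Of the peaks of replicate 1, 71.5% overlapped a peak of replicate 2 by at least 1 bp, and 80.7% did so in the other direction (mean 76.1%). Both directions describe 1 pair of lists of unequal size, so their difference is not a spread between animals. Random placement gave 1.69% and 1.96%. Promoter peaks recurred most often, in 84.7% and 87.3% of cases, compared with 67.9% and 79.3% of intronic peaks and 68.4% and 78.6% of intergenic peaks. Overlap climbed with peak height, from 30.5% and 35.5% in the lowest decile to 99.2% and 99.6% in the highest decile. Over the 80516 paired peaks, the heights of the animals correlated across peaks with a Spearman coefficient of 0.93 and, on the log2 scale, a Pearson coefficient of 0.95. Peaks are not independent replicates, so these coefficients describe the pair of libraries only. Heights differed between animals by a median of -0.37 (log2, replicate 2 minus replicate 1) with an SD of 0.42, and 94.0% of the pairs lay within 2-fold. Covered bases were shared to a lesser degree, with 15.03 of 30.04 Mb (50.01%) open in both animals.

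**Figure D1:**
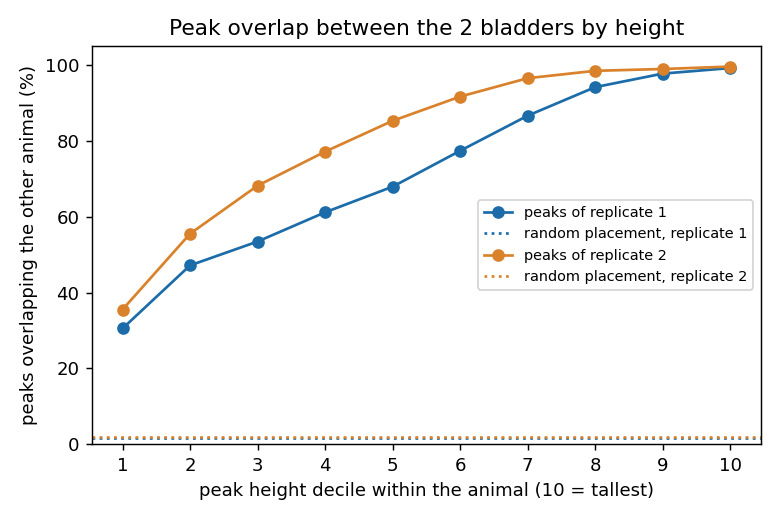
Share of each animal's peaks (vertical axis, percent) that overlapped a peak of the other animal, by decile of peak height (horizontal axis, lowest to highest), with random placement for comparison. The share went from 30.5% to 99.2% in replicate 1 and from 35.5% to 99.6% in replicate 2, against 1.69% and 1.96% by chance.

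Genes of the urothelium, the lining epithelium of the bladder, had open promoters more often than other genes. Of 24 urothelial genes, 21 had a promoter peak in both animals. The share was 95.8% in replicate 1 and 87.5% in replicate 2, against a median of 58.3% for random gene lists matched on gene length (percentiles 100 and 99.9). The uroplakins, membrane proteins of the surface layer, were among them. Upk1a (ENSMUSG00000006313.5, chromosome 7, 30603092 to 30612847, mm10) had a promoter height of 2.25 ± 0.40 (SD, n = 2, as for the heights that follow). Upk2 (ENSMUSG00000041523.3, chromosome 9, 44452715 to 44454976) had 3.20 ± 0.59, and Upk3a (ENSMUSG00000022435.6, chromosome 15, 85017141 to 85022547) had 2.35 ± 1.24. The Upk1a and Upk2 peaks hold a protected stretch with the core consensus of the insulator protein CTCF, at -913 and 656 bp from the gene start. Their heights thus describe sites within the promoter window but away from the gene start itself. Regulators of urothelial differentiation were open as well, with 1.99 ± 0.06 at Pparg, 1.496 ± 0.55 at Foxa1 and 1.54 ± 0.26 at Gata3. The tight junction gene Cldn4 had 3.69 ± 1.31, the adhesion gene Epcam 2.08 ± 0.94, and the basal keratin gene Krt5 1.32 ± 0.54, although its highest promoter peak was not the same peak in the 2 animals. Low peaks stood at Krt20, a keratin of the surface cells (0.50 ± 0.05), and at Trp63, the transcription factor of basal cells (0.40 ± 0.25). The Trp63 peak lay upstream of the most upstream annotated start, and 15 and 8 peaks lay elsewhere in and around the gene. A start further inside Trp63 was not examined by this measure. The remaining 3 members, chosen after their values were seen, were Krt19 and Psca, with a promoter peak in replicate 1 only, and Krt7, with none. With the smaller peak list the urothelial share was 72.9% and no longer stood apart.

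All 14 housekeeping genes had an open promoter in both animals (100% against 57.1%, percentiles 100 and 100). The cytoskeletal gene Actb had a height of 12.5 ± 5.36, the glycolytic gene Gapdh 8.76 ± 4.40 and the X-linked glycolytic gene Pgk1 3.10 ± 1.25. Against random lists matched on promoter GC content, the housekeeping percentiles were 97.495 and 98.01, below the threshold of 99, while urothelium had 99.98 and 99.1.

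Smooth muscle and fibroblast genes were open in proportions similar to urothelial genes without passing the threshold in both animals. Of 16 smooth muscle genes, 13 had a promoter peak in both animals (percentiles 84.9 and 99.1), and of 14 fibroblast genes, 13 did (97.48 and 97.9). Among contractile genes, Myh11 (ENSMUSG00000018830.10, chromosome 16, 14194535 to 14291372) had a height of 2.15 ± 0.95, Acta2 had 0.79 ± 0.12 and Actg2, the enteric and visceral actin, had 0.45 ± 0.16. The small heat shock gene Hspb6 reached 8.07 ± 1.10, the highest of the named smooth muscle genes. The collagen gene Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) had 4.66 ± 0.66, the growth factor receptor gene Pdgfra 2.25 ± 0.65 and the proteoglycan gene Lum 0.38 ± 0.10. The Col1a1 peak also lies away from the gene start and holds a protected stretch with the CTCF core, 959 bp from it. The Pdgfra peak lies away from the start too, with a protected stretch without that core at -980 bp. With lists matched on promoter GC content, the fibroblast list passed, at percentiles of 99.99 and 100. Endothelium had 9 of 15 genes open in both animals (64.5 and 24.5), with 2.68 ± 1.16 at the junction gene Esam. Pecam1, the endothelial adhesion gene, had no peak at its most upstream annotated start but 18 and 12 peaks elsewhere in and around the gene. The mesothelial list had 3 of 6 genes open (84.0 and 28.4), including Upk3b at 1.81 ± 0.61. Upk3b is itself a uroplakin gene, so this list may not stand for mesothelium alone. The glia and nerve list had 5 of 10 open (19.96 and 69.4), including the myelin gene Mbp at 2.90 ± 1.43.

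Genes of blood cells and of distant organs were open less often than random genes in 6 lists. Immune genes had a promoter peak in both animals in 3 of 15 cases (percentiles 0.14 and 0.91), and the pan-leukocyte gene Ptprc had none. The macrophage gene Adgre1 had a low peak of 0.51 ± 0.07. Liver genes were open in 2 of 14 cases (0.54 and 0.01), erythroid genes in 2 of 10 (0.52 and 0.68), pancreas and gut genes in 1 of 12 (0.19 and 0.03), retina genes in 1 of 10 (0.02 and 0.04) and germ cell genes in 2 of 10 (0.30 and 0.35). No promoter peak was called at the albumin gene Alb or at the most upstream annotated start of the insulin gene Ins2. The Ins2 model is long (chromosome 7, 142678656 to 142743381) and held 7 distal peaks in each animal. A start further inside the model was therefore not examined by this measure. Germ cell gene Dazl had 4.69 ± 1.24 and the erythropoietin receptor gene Epor had 1.65 ± 0.66, so these lists were not uniformly without peaks in the promoter window. Both peaks lay away from the gene start. In replicate 1 the Dazl peak was at 50292721 to 50292940 for a start at 50293636, and the Epor peak at 21962501 to 21962720 for a start at 21963506. Neuronal genes were open in 5 of 14 cases (1.56 and 1.94), skeletal muscle genes in 6 of 12 (41.04 and 23.3) and heart genes in 4 of 10 (29.6 and 13.6), and these lists did not pass. With the higher 50% of the peaks, neuronal (21.4%) and heart genes (10%) also lay below the threshold. With random lists matched on promoter GC content, 3 of the 6 lists stayed below the threshold, and immune (0.73 and 4.80), liver (4.17 and 0.14) and erythroid genes (3.94 and 4.79) did not. The erythroid call was kept in 3 of 8 alternative settings and was also lost with both other promoter windows, the higher 50% of the peaks and the smaller list. With a promoter window of 2 kb, only immune and pancreas and gut genes, 2 lists, were below the threshold, and retina genes also lost their call with any annotated transcript start.

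**Figure D2:**
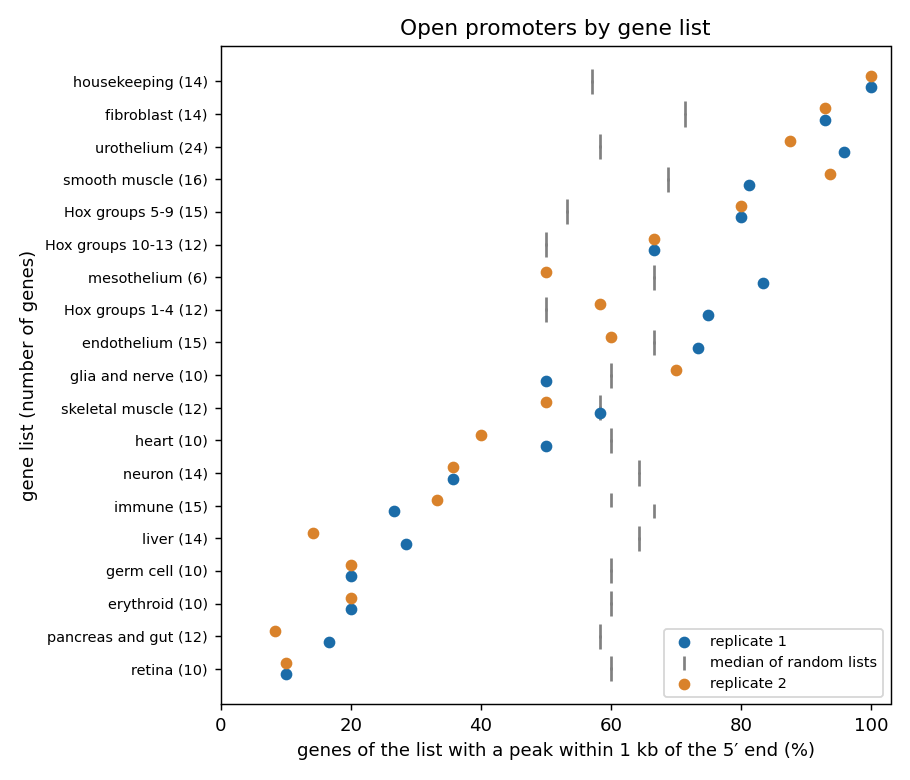
Share of the genes of each list (vertical axis, number of genes in brackets) with a peak within 1 kb of the 5′ end (horizontal axis, percent), as 1 point per animal, with grey marks at the medians of random lists matched on gene length. Urothelial genes reached 95.8% and 87.5% against 58.3%, while retina genes had 10% in both animals against 60%.

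With the main peak list, Hox genes, which set position along the body axis, had the densest distal open sites of any list. Hox groups 5 to 9 had a median of 2.66 ± 0.18 distal peaks per 10 kb (SD, n = 2), 5.68 and 5.57 times the median of random lists. Groups 10 to 13, the genes of the caudal body, had 2.26 ± 0.50, which was 3.95 and 5.80 times random. Both lists passed in both animals (percentiles 100 and 100, and 99.8 and 100). Because the 27 genes lie in 4 clusters and their surroundings overlap, random runs of neighbouring genes were also drawn, in a comparison chosen after the data were seen. The percentiles were then 100 and 99.99 for groups 5 to 9, and 99.5 and 100 for groups 10 to 13. The runs were not matched on gene spacing, while the surroundings of the 27 genes merge into 5 domains, so the overlap is only partly allowed for. Promoters of neighbouring genes count as distal peaks, so the close packing of Hox genes may add to these densities. With the smaller peak list, groups 10 to 13 had 0.678 distal peaks per 10 kb, below smooth muscle genes, and lost their call. Hoxa9 (ENSMUSG00000038227.15, chromosome 6, 52223100 to 52231089) had 11.7 ± 3.54 distal peaks per 10 kb, Hoxa7 9.07 in each animal, Hoxa11 8.98 ± 0.98 and Hoxa10 8.68 ± 0.51. Hoxa13 (ENSMUSG00000038203.18, chromosome 6, 52257694 to 52260880) had a promoter height of 1.72 ± 0.12. Hoxd13 had a promoter peak of 0.80 in replicate 2 and none in replicate 1, and Hoxc12 had none. Promoters of the Hox groups did not stand apart as lists, with 12 of 15 open in both animals for groups 5 to 9 (percentiles 98.7 and 98.9), 7 of 12 for groups 10 to 13 (89.2 and 90.6) and 7 of 12 for groups 1 to 4 (93.4 and 65.4). Groups 1 to 4 had a distal density of 1.45 ± 0.06 (98.9 and 99.8) and missed the threshold in replicate 1.

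**Figure D3:**
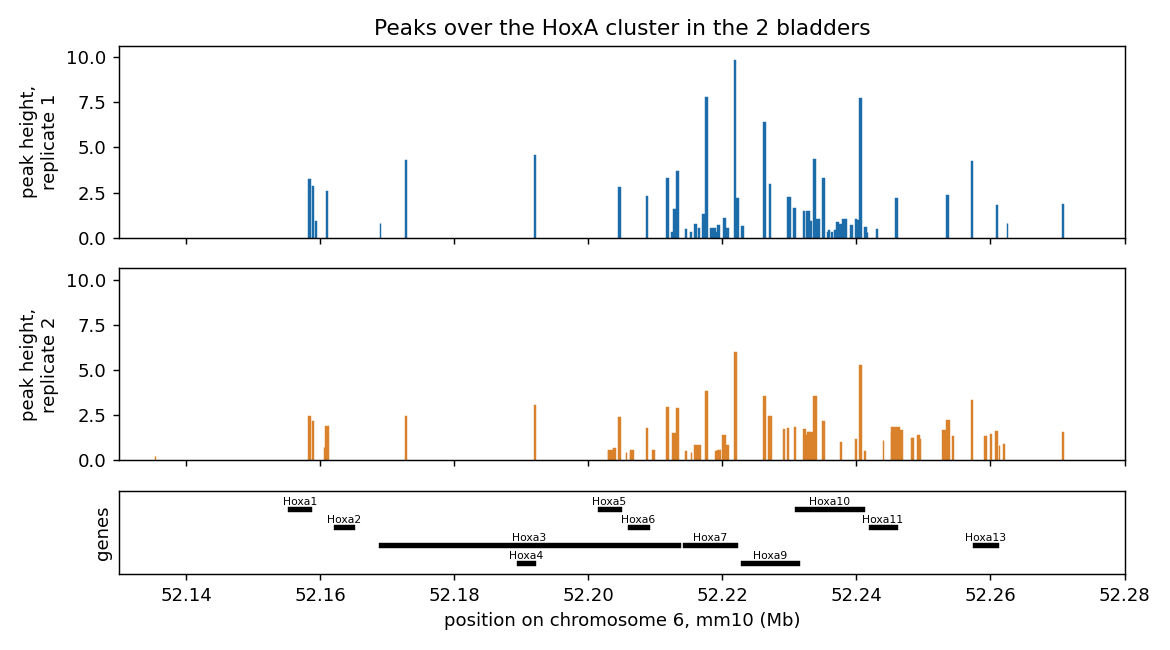
Map of the HoxA cluster on mouse chromosome 6 (horizontal axis, position in Mb, mm10) with the height of each peak in both animals (vertical axis, the authors' value) and the genes below. Replicate 1 had 59 peaks and replicate 2 had 63, with the highest peaks at 9.83 and 6.00.

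Outside the Hox clusters, no list passed the threshold for distal density in both animals. The urothelial list had 1.07 ± 0.24 distal peaks per 10 kb (SD, n = 2; percentiles 99.7 and 98.1) and smooth muscle 1.07 ± 0.22 (99.7 and 98.8), so each passed in replicate 1 only. Housekeeping genes had 1.27 ± 0.15 (98.7 and 98.4), the highest density outside the Hox lists, and passed with a window of 50 kb around the gene (1.503). Smooth muscle passed with the smaller peak list (0.732) and with the same window (1.05), and urothelium with the higher 50% of the peaks (0.849). Foxa1 (ENSMUSG00000035451.7, chromosome 12, 57540628 to 57546916), a forkhead factor of endodermal epithelia, had 6.79 ± 0.87, the highest density of the urothelial list. The corresponding values were 3.53 ± 1.43 at Cldn4, 2.40 ± 0.26 at the smooth muscle gene Tpm2 and 2.27 ± 0.55 at Pdgfra. The other stromal and nerve lists lay between the thresholds, with percentiles of 96.7 and 93.0 for fibroblast, 87.6 and 37.5 for endothelium, 81.7 and 97.0 for mesothelium, and 57.4 and 85.2 for glia and nerve. The same held for immune (23.97 and 10.3), liver (26.2 and 39.7), neuron (60.2 and 70.9), skeletal muscle (62.4 and 62.2), heart (66.3 and 64.2), erythroid (23.6 and 32.6), pancreas and gut (54.8 and 6.82), retina (22.7 and 17.3) and germ cell genes (17.9 and 24.9). The genes with the most distal peaks found in both animals were long, led by the readthrough model Gm20388 with 425, the fibroblast growth factor receptor gene Fgfr2 with 171 and Gse1 with 55. The Fgfr2 model spans 130162451 to 133123350 on chromosome 7, and its density was ordinary, at 0.72 ± 0.06 per 10 kb (percentile 61.0 of all genes). Gse1 lies inside Gm20388, so its peaks are counted for both. They were followed by Pde4d (47), Auts2 (46), Lrmda (44), Rora (44), Zfhx3 (42), Camta1 (41) and Nav2 (41). Counted over all 19 lists, the Hox lists included, 5 passed with a window of 50 kb around the gene. With the higher 50% of the peaks, or with replicate 1 alone, 4 of the 19 did.

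Urothelial genes carried less open signal in replicate 2 than in replicate 1, relative to other genes. Summed peak height over each gene and 10 kb on either side had a median difference of -0.48 over all genes (log2, replicate 2 minus replicate 1), and this was subtracted. The urothelial median was then -0.27 (quartiles -0.43 and -0.01, 18 of 24 genes higher in replicate 1, percentile 0.01). Differences were -0.84 at Trp63, -0.69 at Krt5, -0.45 at Gata3, -0.42 at Upk3a, -0.16 at Upk1a and -0.07 at Upk2, while Foxa1 had 0.53. Urothelial genes held 174 peaks over 35.4 kb in replicate 1 and 151 peaks over 36.0 kb in replicate 2, with mean heights of 1.72 and 1.22. The ratio of mean heights was 0.71 for urothelium and 0.77 for all genes. Smooth muscle (-0.09, percentile 17.2), fibroblast (-0.06, 13.99) and endothelial genes (0.00, 22.2) did not stand apart. In other settings, fibroblast genes were called low with quantile scaling (-0.22, percentile 0.40), and endothelial genes with 1 kb around the gene start (-0.06, 0.85) and with the smaller peak list (-0.29, 0.07). Hox groups 5 to 9 (0.14, percentile 99.9) and 10 to 13 (0.27, 99.5) passed in the opposite direction, with 1.37 at Hoxa13 and 1.47 at Hoxd13. Groups 5 to 9 held 78 and 74 peaks over 17.6 and 18.3 kb with mean heights of 2.19 and 1.73, and groups 10 to 13 held 61 and 67 peaks over 12.7 and 14.5 kb with 1.86 and 1.53. Groups 10 to 13 lost their call in each of the 5 settings planned beforehand, and groups 5 to 9 with 1 kb around the gene start and with quantile scaling. The Hox calls also ended against random runs of neighbouring genes (percentiles 87.2 and 98.0) and when only peaks found in both animals were used (96.1 and 84.3). The urothelial call ended with 1 kb around the gene start (2.33), with peak counts in place of heights (2.36) and with a pseudocount of 10 (3.57). With peaks found in both animals the urothelial median was -0.14 (percentile 0.12).

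The other lists did not stand apart in this difference, although pancreas and gut genes were called low when peaks were counted (-0.74). Their medians were 0.05 for immune (percentile 31.9), 0.21 for glia and nerve (89.4), 0.12 for mesothelium (41.8), -0.13 for housekeeping (21.9), 0.04 for liver (8.43) and 0.20 for neuron (84.6). Values for skeletal muscle (0.00, 20.8), heart (0.10, 21.1), erythroid (0.03, 33.9), pancreas and gut (0.03, 12.0), retina (0.01, 12.5), germ cell (0.13, 75.7) and Hox groups 1 to 4 (0.06, 73.9) also lay between the thresholds. How the authors scaled peak height is not given in the sources used here, so these differences are relative and carry no error between animals.

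The highest peaks found in both animals lay mostly away from promoters. The first, at chromosome 17, 39846781 to 39846900 in replicate 1, had heights of 62.7 and 92.2. It lies 103679 bp from the start of Esp38, the nearest protein-coding gene, and inside a ribosomal RNA gene of the GENCODE annotation, CT010467.1. The second lies in an exon of Lars2, a mitochondrial leucyl-tRNA synthetase gene, nearest the start of Limd1 (chromosome 9, 123461901 to 123462100, 43.7 ± 4.93, SD, n = 2). The third lies in an intron of Il31ra, an interleukin receptor gene (39.2 ± 2.20). Promoter peaks among them were those at the cold-sensing channel gene Trpm8 (35.8 ± 13.2) and the dynein light chain gene Dynlt1b (35.0 ± 15.2). The Trpm8 peak also lies on another protein-coding gene, Hjurp, so it cannot be assigned to Trpm8 alone. The others were intergenic peaks nearest Igf2bp3 (37.8 ± 2.57) and Gm8797 (36.5 ± 6.39), an intronic peak of Kpna1 (34.5 ± 1.00), an exonic peak of Cers5 nearest the start of Cox14 (32.9 ± 0.38) and an intronic peak of Zc3h7a nearest Txndc11 (30.02 ± 7.82).

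Peaks seen in a single animal were narrow and low. In replicate 1, 26961 peaks (22.9%) overlapped no peak and no region at a false discovery rate up to 0.05 of the other animal, and in replicate 2 there were 16955 (16.5%). Their median heights were 0.489 and 0.374, their median widths 129 and 115 bp, and their mean GC contents 51.9% and 51.2%, against 55.5% and 55.3% for the other peaks. The highest in replicate 1 were an intronic peak of Gsn, an actin-severing protein gene (3.92), an intronic peak of Cuedc1 nearest the start of Mrps23 (3.15), and peaks nearest Zfp36l1 (2.94), Pnpla2 (2.84) and Epb41l4b (2.73). In replicate 2 they were an intronic peak of Bahcc1 (1.80), an exonic peak of Hoxa9 (1.76), a peak nearest Bcl6b (1.72), and a promoter and an intergenic peak nearest Hoxa11 (1.71 and 1.68).

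Few open sites lay on the Y chromosome, and the labels give both animals as female. Y had 0.374 and 0.363 peaks per Mb, X had 17.5 and 15.3, and autosomes had 47.9 and 41.8. On Y, 33 peaks were called in replicate 1 and 32 in replicate 2, of which 19 overlapped. Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the RNA that coats the inactive X, had open promoters with heights of 2.32 and 1.14. The ratio of X to autosomal peak density was 0.365 in both animals, and 0.242 for the higher 50% of the peaks.

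Footprints, the short protected stretches inside open regions, were called within most peaks but recurred less than the peaks themselves. There were 280105 footprints in replicate 1 and 247833 in replicate 2 (263969 ± 22820, SD, n = 2), with median lengths of 10 and 9 bp. Of these, 89.5% and 87.6% lay in peaks, and 81.0% and 74.9% of the peaks held at least 1. Footprints overlapped one of the other animal in 44.8% and 52.2% of cases. Within peaks the overlap was 45.1% and 54.4%, against 29.2% and 32.5% when footprints were placed at random in the same peak. The mean ratio over the 2 directions of this comparison was 1.61. At the promoter of Upk1a the longest stretch protected in both animals was TCTCGGACAGCGCCCTCTGGTGGTCGCT (chromosome 7, 30613746 to 30613773, upstream of the gene). At Upk2 it was TCTGACCACCAGATGGCAGGCTTGAGCTG (chromosome 9, 44454306 to 44454334, within the gene). Both contain the core consensus of CTCF, the insulator protein, as does TGCCCGCCACCTAGTGGTTGCCTT at Col1a1 (chromosome 11, 94937171 to 94937194). At Upk3a the longest common stretch was 7 bp, GAGAGGG (chromosome 15, 85017118 to 85017124), without that core. The Myh11 stretch, CCTTCGCGGCGCCCCCTGCAGGTGAG (chromosome 16, 14291464 to 14291489), the Pdgfra stretch GTCAGCGCCCCCTTT (chromosome 5, 75151305 to 75151319) and the Foxa1 stretch TCCTCCTCCTCCC (chromosome 12, 57546971 to 57546983) do not. Stretches were picked by length after the data were seen, and at 50% reciprocal overlap 32.1% and 36.3% of the footprints recurred.

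Recognition sequences of broadly used factors were concentrated in footprints. Of 22 motifs, 10 were enriched against the rest of the same peaks in both animals. The ratios of matches per Mb were 48.4 and 61.5 for NRF1, a regulator of mitochondrial genes, with 95% intervals of 34.0 to 77.4 and 41.7 to 106. They were 26.7 (24.3 to 29.1) and 24.1 (22.0 to 26.4) for CTCF, and 27.5 (15.6 to 53.5) and 21.01 (12.7 to 36.7) for REST, a repressor of neuronal genes that had been listed as foreign to the tissue. NFI had 15.7 and 9.19, RFX 8.83 and 11.1, SP and KLF factors 7.60 and 7.65, and ETS factors 5.40 and 6.67. Smaller enrichments were found for NF-Y (1.57 and 1.86), the TCF21-type E-box (1.28 and 1.37) and AP-1 (1.20 and 1.12). Depleted motifs were those of forkhead factors (0.458 and 0.495), GATA factors (0.649 and 0.672) and RUNX (0.79996 and 0.771). Their reversed forms were depleted too (0.708 and 0.711, 0.535 and 0.673, and 0.725 and 0.476). The depletion of GATA and RUNX motifs is therefore not specific to these sequences as written, and neither is part of that of forkhead motifs. TEAD, SRF, grainyhead-like, p53 family, PPAR, MEF2, HOX group 13 and HNF1 motifs were not called, and the CRX motif had too few matches. AP-1 turned to depletion (0.860) when footprints were not extended by 5 bp, and RFX lost its call in distal peaks alone (8.54). The consensus of SP and KLF factors is counted equally when reversed, so the control with reversed motifs says nothing about it.

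**Figure D4:**
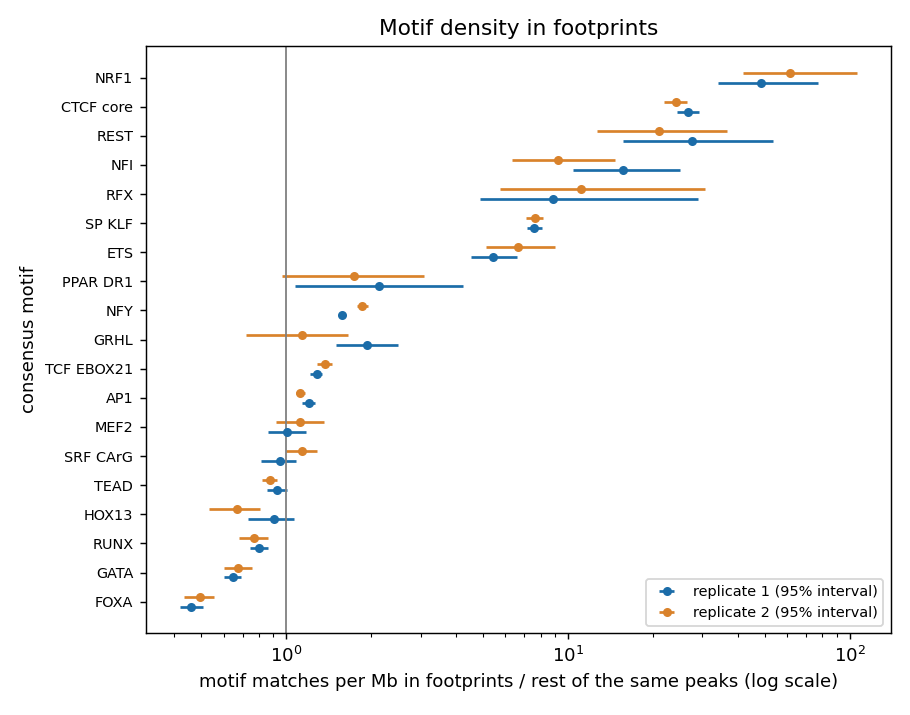
Ratio of motif matches per Mb in footprints against the rest of the same peaks (horizontal axis, log scale) for each motif and animal, with 95% intervals from bootstrap draws of chromosomes; p53 family and HNF1 motifs, whose intervals reach 0, and the CRX motif are not drawn. NRF1 (48.4 and 61.5), REST (27.5 and 21.01) and CTCF (26.7 and 24.1) lie farthest to the right, and forkhead motifs (0.458 and 0.495) farthest to the left among the called motifs.

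Open sites at promoters and away from them shared several enriched motifs, measured against flanking DNA in peaks found in both animals. ETS motifs were enriched 16.2 and 15.7 times at promoters and 3.09 and 2.63 times in distal peaks. SP and KLF motifs had 18.0 and 14.7 at promoters and 3.95 and 3.70 in distal peaks, and NRF1 had 198 and 106, on 2 and 3 flank matches, and 8.84 and 6.46. The motif of grainyhead-like factors, regulators of epithelia, had 2.30 and 1.91 at promoters and 4.41 and 4.55 in distal peaks, and CTCF had 17.6 and 13.1 at promoters and 139 and 129 in distal peaks. AP-1 was enriched in distal peaks, at 3.52 and 3.19, while at promoters it had 1.01 and 0.913 with intervals that spanned 1. TEAD (1.57 and 1.55) and forkhead motifs (1.21 and 1.17) were enriched in distal peaks and depleted at promoters, with 0.650 and 0.643 for TEAD and 0.564 and 0.549 for forkhead factors. Over all shared peaks 12 motifs were enriched and 5 depleted, with CTCF at 110 and 101, AP-1 at 2.99 and 2.71, grainyhead-like factors at 3.77 and 3.64 and HOX group 13 at 0.539 and 0.531. REST had 87.4 and 85.0 on 2 flank matches in each animal. The reversed grainyhead-like motif was also enriched, at 2.17 and 2.05, so part of its excess does not depend on the sequence as written, and the reversed HOX group 13 motif was as depleted (0.552 and 0.533) as the motif itself. Over all shared peaks the reversed TEAD (0.733 and 0.739) and forkhead motifs (0.577 and 0.589) were depleted, and reversed motifs were not counted at promoters alone, so the depletion there may not be specific to these motifs. The difference between distal and promoter peaks was not itself tested.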

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

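The comparisons with overlap against regions at a false discovery rate up to 0.05, and, for the difference between animals, with scaling by GC content and with peaks shared by both animals were chosen after the results were seen. The other settings compared in this part were planned. No paired analysis was possible because the series has 1 group and no second condition to pair with. Of 695 combinations of a result and an alternative setting, those of the main results numbered 74 that kept their call or stayed close to the main value, 35 that moved and 1 that gained a call. For single lists and motifs, 525 kept their call, 31 lost it, 28 gained one and 1 reversed: AP-1 in footprints, at 0.860 without the extension of footprints. Except where stated, the cause was not tested. The smaller peak list gave 67482 peaks per animal, a correlation of 0.94, 27.3% promoter peaks, an X to autosome ratio of 0.340, 1 list above the threshold for promoters, and 1 above and 2 below for the difference between animals. The higher 50% of the peaks gave, by construction, 55110.5 peaks per animal. It also gave an overlap of 84.7%, a correlation of 0.90, 30.03% promoter peaks, a ratio of 0.242, 4 lists above for distal density and a call for Hox 5 to 9 promoters (80%). Reciprocal overlap of 50%, a stricter criterion, gave 60.8% for peaks and 34.2% for footprints. A narrower promoter window gave 14.3% promoter peaks and a window of 2 kb gave 24.7%, as their widths set, and 2 kb gave 2 lists below. Matching on promoter GC content left 3 lists below. A domain of 50 kb gave 5 lists above for distal density, and leaving out a replicate gave 3 to 4. For the difference between animals, 1 kb around the gene start gave 0 lists above, peak counts 1, quantile scaling 0 above and 2 below, a pseudocount of 10 gave 1 above and 0 below, and peaks shared by both animals 0 above. Without the extension, 6 motifs were depleted in footprints, and with a replicate left out 3 to 5. Reversed motifs gave 1 enriched and 8 depleted in footprints, and 2 enriched and 10 depleted in peaks. Flanks at 5 kb gave 3 depleted. Alternatives that rank footprints by a score were not run because the deposited value is constant. Differences between lists of under 2-fold in distal density were often missed at 14 genes in the simulation (77.5% called at 2 times, 40% at 1.5 times). It raised genes of low density to the median first and used a single library, so more may be missed under the rule used here. Low peaks, of which 30.5% and 35.5% recurred in the lowest height decile, limit statements about weak sites.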

Other observations

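Of the tests here, the ratio of X-linked to autosomal promoter height, scaling by GC content, quantile scaling of the Hox genes against random runs, the added lists of epithelial, developmental and escape genes, and all repeats with peaks found in both animals were chosen after the results were seen. Quantile scaling of the urothelial list was planned, but what it should show was written after the results were seen. Genes on the X chromosome had lower promoter peaks than autosomal genes, a group not described above. Of 948 X-linked protein-coding genes, 46.8% in replicate 1 and 45.7% in replicate 2 had a promoter peak, against 65.8% and 64.8% of autosomal genes. For the 413 with a peak in both animals, counted without the escape genes described next, the median height was 2.48 and 1.76. Autosomal promoters of the same GC content had 4.58 and 3.37. The ratios were 0.541 (95% interval 0.479 to 0.626) and 0.522 (0.473 to 0.588). These intervals come from 1000 random draws of autosomal genes and leave out the spread of the X-linked genes.

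Genes known to escape X inactivation had high promoter peaks in both animals. The histone demethylase genes Kdm6a (chromosome X, 18162575 to 18279936, mm10) and Kdm5c had heights of 16.5 ± 7.95 and 7.81 ± 4.48 (SD, n = 2). The RNA helicase gene Ddx3x had 6.84 ± 1.81, Pbdc1 5.90 ± 1.97 and the translation factor gene Eif2s3x 4.78 ± 0.41, while Mid1 had only 0.50 ± 0.07. The median of the 6 genes was 7.71 and 4.58, or 1.68 and 1.36 times the autosomal medians of 4.58 and 3.37. Those autosomal promoters were matched to the GC content of the other X-linked genes and not to that of the escape genes.

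A candidate explanation for the low X-linked promoters is that 1 of the 2 X chromosomes is closed in females, for which the mean ratio over the animals was 0.532, near the level a closed copy would give. A general shortage of X-linked reads, as from mapping, would lower the escape genes too, but their median lay at percentile 99.99 or above of random X-linked lists in both animals (99.97 and 99.98 with lists matched on GC content). The escape genes are broadly expressed, so their high promoters may also reflect strong activity, and Mid1 did not follow the others. No male bladder was analysed here, so lower activity of X-linked genes on both copies remains open, and the closed X chromosome stays a hypothesis.

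The animals differed at urothelial genes, lower in replicate 2, a call that ended with 1 kb around the gene start (-0.02, percentile 2.33), peak counts (2.36) and a pseudocount of 10 (-0.08, 3.57), and more weakly at Hox genes of groups 5 to 13, which lay at percentile 96.5 of random runs of neighbouring genes as deposited and at 68.03 with peaks found in both animals. Scaling heights by GC content left urothelium at percentile 0 (median -0.27) and Hox at 99.6 (0.22), which argues against a GC effect on the heights of called peaks. The scaling cannot reach a GC effect on which peaks were called, so an effect of that kind stays open, above all for Hox, which rested on peaks not found in both animals. Quantile scaling left urothelium at percentile 0 (-0.31) but Hox at 97.4, so the height distribution stays open for Hox. A second list of 30 epithelial genes, written before it was looked at, lay at percentile 0 (median -0.28 over 29 genes with signal, covering 46.2 and 42.4 kb with mean heights of 2.09 and 1.54), and at 0.03 with peaks found in both animals, as a smaller epithelial share in replicate 2 would give. The stromal lists did not rise past the threshold (medians of -0.09 for smooth muscle and -0.06 for fibroblast, or 0.08 and 0.12 with shared peaks). Fibroblast genes were themselves called low with quantile scaling (-0.22, percentile 0.40), and endothelial genes with 1 kb around the gene start (-0.06, 0.85) and with the smaller peak list (-0.29, 0.07), so low calls were not confined to epithelial genes. Digestion and library preparation were not tested, so no biological cause is claimed. A list of 68 other developmental regulators lay at percentile 100 (median 0.42, 48 of 63 genes higher in replicate 2, covering 50.5 and 78.3 kb with mean heights of 1.22 and 0.91), which may mean that such genes as a class had more called sites there, but at 91.1 with peaks found in both animals, where the call ended.

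The highest shared peaks away from promoters may in part hold reads of a high-copy sequence collapsed on few reference copies. Of 8 such peaks, 4 matched at least 5 places in the reference chromosomes at 90% identity over 80% of their length. The criterion set in advance asked for 5 peaks and named places of the reference and annotated ribosomal RNA. The count is 5, which meets it, if matches outside the assembled chromosomes are included or if the GENCODE ribosomal RNA gene at the first peak is, so collapsed copies and strong openness cannot be told apart for the peaks as a set. The criterion for CTCF binding sites also asked for 5 peaks, and the core consensus was found in 0 of 8, which did not meet it. Only exact matches were counted, so sites that depart from the consensus would be missed and CTCF binding is not excluded.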
